A study of Homo sapiens with 12 samples.

How the data were processed

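RNA from primary human monocytes and from macrophages derived from them was measured on Affymetrix oligonucleotide arrays, 1 array per sample and 12 arrays in all. Monocytes were isolated from human blood mononuclear cells and grown in a serum-free macrophage medium, and macrophages were obtained by adding M-CSF (macrophage colony-stimulating factor, the ligand of the receptor CSF1R), per the labels' protocols. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The labels name 6 donors, each with 1 array labelled monocyte and 1 labelled macrophage. The time in culture is not given in the sources used here.

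The deposited table holds 1 value on the log2 scale for each of 33297 transcript clusters (groups of probes that cover one transcript locus) and each array. RMA (robust multi-array average, which corrects background, normalizes between arrays and combines probes) and Partek are named in the submitters' processing notes, with no version, setting or order of steps. The log2 scale is not written in the deposited file: it was read from the values, which ran from 2.14 to 13.9 with no value missing. Array medians ran from 6.15 to 6.34, 25th percentiles from 4.66 to 4.84 and 75th percentiles from 7.73 to 7.91, so the arrays were close in distribution but not identical in it. Genes were not centred. No detection calls or array background values were used, so a low value could not be told from background, and the number of arrays limits the precision.

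Clusters were named from the annotation of the array platform: 19460 had 1 gene symbol, 1754 had several and were left out, and 12083 were not listed in that annotation and stayed unnamed. Symbols were updated through their Entrez number in a RefSeq gene table of the assembly GRCh38.p14, which held 19429 of the 19460. Where a gene had more than 1 cluster (769 genes), the one with the highest mean over the 12 arrays stood for it, which left 18417 genes. No coordinates are given because the build behind the clusters is not given in the sources used here. Genes whose level can follow the sex or genotype of a donor (37 genes on the array, among them Y-linked genes and antigen receptor segments) took part in the fit but are neither named nor shown. A shared or homologous probe can carry signal from a paralog, which applies to the MHC class II, haemoglobin and metallothionein genes below.

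The comparison was macrophage minus monocyte by label, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the 18417 genes, threshold 0.05). The fit, its alternatives, the rule for named genes and 35 gene lists were fixed before the data were examined. The lists cover monocyte and macrophage markers, metabolism, immune response and the other cell types a monocyte isolate can hold. Of their 716 distinct genes, 652 were measured and the rest were not analysed here. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, with camera at an estimated correlation and fry (which tests whether the genes of a list move one way on balance) beside it. The rule for named genes took the 10 genes with the largest positive and the 10 with the largest negative difference among those past the threshold with 1 sign in all 6 donor pairs, up to 4 members per list past the threshold or, in a list with none, the 2 with the largest absolute difference, and CSF1R, CSF1, CD14, CD68 and ACTB whatever their values. The list rule and the fixed genes gave 70 names. Any other gene named below was chosen after its values were seen, and the text says so.

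Alternatives were a replicate block for the donor number, a filter that kept genes above the array median in at least 6 arrays, quantile normalization of the deposited values once more, centring of each array on its median, the mean of a gene's clusters, eBayes with trend and robust settings, array weights, all clusters tested one by one, a Welch statistic per gene (a separate variance for each gene and label), an adjusted p of 0.01, leaving out each array in turn, camera with ranks and, chosen after seeing the data, the first 2 principal components as covariates and the estimated correlation in each other fit. The donor numbers pair the arrays by the labels. As a check, the deviations of same-numbered arrays from their label means were correlated over genes: Pearson's r ran from -0.62 to 0.05 over the 6 donor numbers (median -0.40), and exceeded 0.1 for 0 of them.

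The fit was tested on simulated data. When 200 of the 18417 genes were changed by label in the real arrays, it recovered 75.0% of changes of 1 on the log2 scale, 95.0% of changes of 2 and 98.3% of changes of 3, and called 0 other genes. In independent noise the shares were 72.5%, 93.3% and 98.3%, with 14 other genes called. With the replicate block in the real arrays the shares were 47.5%, 93.3% and 96.7%. With the 2 components as covariates they were 96.2%, 100% and 100%, with 1 other gene called. The changed genes were drawn at random from all genes, whose median SD within a label was 0.243. These shares do not carry over to genes that vary more, such as the macrophage markers below (median SD within a label 1.87). A lysosome list raised by 0.5 in independent noise gave an adjusted p of 1.34e-16 with camera's preset correlation and 0.000178 with the estimated one. No list was raised in the real arrays, where the genes of a list can move together. What camera with the estimated correlation can find there was therefore not tested. Component scores, gaps between sorted values, most similar arrays and the share of the variance between labels were computed without the 37 genes above, while the fits of other splits of the arrays used all 18417 genes. Correlations between arrays used all clusters without those genes and ran from 0.938 to 0.993, and no 2 arrays held identical values. Nothing in the labels gives a scan date or batch.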

Results

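Human blood monocytes and monocyte-derived macrophages were compared on 12 arrays, 6 under each label. By the labels, each of 6 donors gave 1 array of each label. Same-numbered arrays did not deviate together (median Pearson's r -0.40), so the donor pairs below are pairs by label only. The labels pose 1 question: which genes differ between monocytes that received no M-CSF and macrophages grown with it. Each value is the deposited RMA value on the log2 scale, so a difference of 1 is 2-fold. Differences are given as macrophage minus monocyte, by label, with the standard error of the limma fit or its 95% interval. The conditions are called by their labels throughout, because the values of marker genes did not follow the labels, as described next.

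Genes that monocytes and macrophages both express at high level had nearly equal values under both labels. CSF1R, the M-CSF receptor, was at 10.64 ± 0.36 (SD, n = 6) in arrays labelled monocyte and 10.63 ± 0.23 (SD, n = 6) in arrays labelled macrophage. CD14, the lipopolysaccharide co-receptor, was at 12.07 ± 0.35 and 12.15 ± 0.12. CD68, a lysosomal glycoprotein, was at 12.76 ± 0.27 and 12.75 ± 0.29, and ACTB, cytoplasmic actin, at 12.92 ± 0.10 and 12.88 ± 0.08 (SD, n = 6 each). SPP1 (osteopontin), chosen after its values were seen, had close means with a very wide spread. It averaged 10.17 ± 4.28 in arrays labelled monocyte and 10.10 ± 3.97 in arrays labelled macrophage (SD, n = 6 each). Under each label it was low in 2 arrays, between 4.55 and 5.14 over both labels, and between 12.3 and 13.1 in the other 4.

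**Figure D1:**
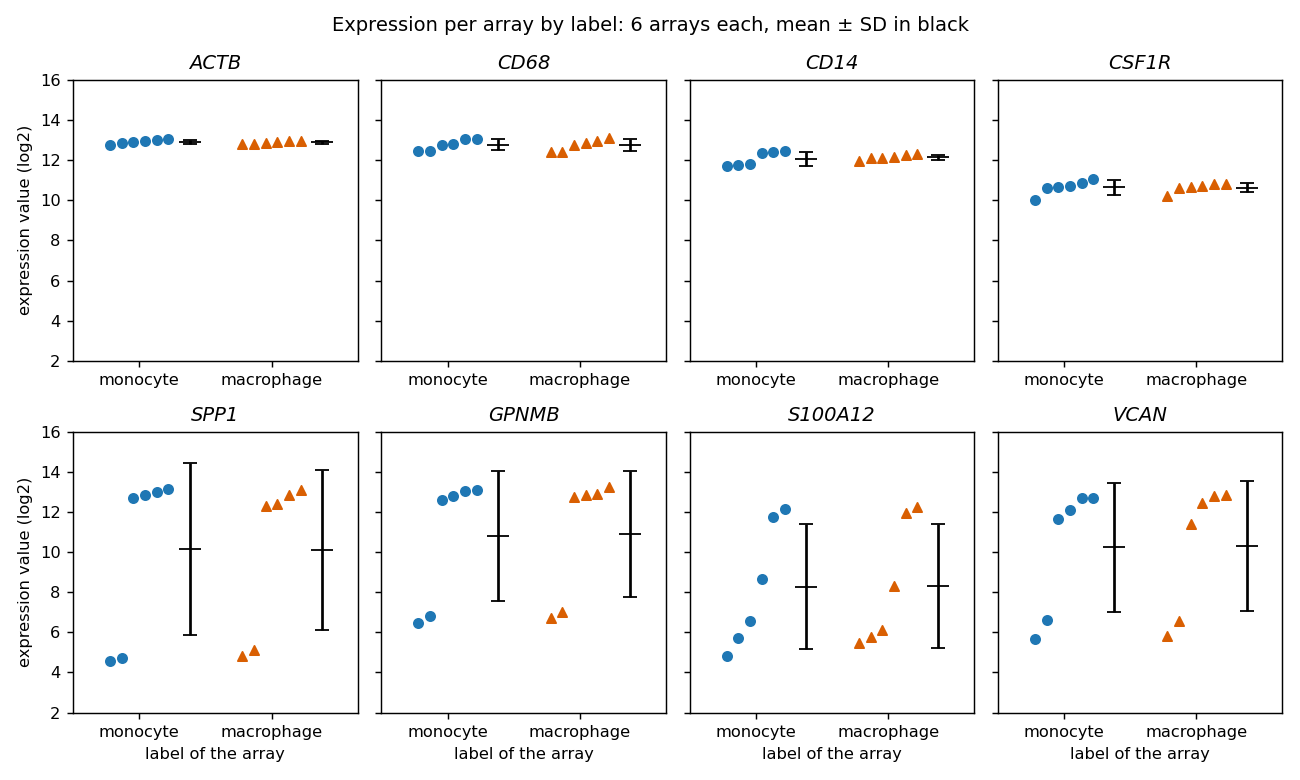
Expression values (log2, vertical axis) of 8 genes by the label of the array, with 1 point per array (n = 6 per label, in ascending order) and the mean ± SD in black. ACTB, CD68, CD14 and CSF1R lie at one level under both labels, while SPP1, GPNMB and VCAN each have 2 low and 4 high arrays under each label and S100A12 has 2 arrays above 11.7 under each label. Arrays are sorted anew for each gene, so the low arrays of 1 gene need not be those of another. On the first principal component, described below, VCAN (-2.37) lies opposite to SPP1 (3.76) and GPNMB (2.96).

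No gene passed the test for a difference between the labels. Of 18417 genes, 0 passed an adjusted p of 0.05 in the limma fit, and 0 passed it with the donor number as a replicate block or with a separate variance for each gene and label. At an unadjusted p under 0.05 the limma fit held 117 genes, 50 higher and 67 lower in arrays labelled macrophage, where the threshold alone gives 921. That number is a poor reference for arrays that fall into clusters. Of 100 splits of the arrays, the real one included, 13 held as few genes, and the median of the others was 415. The balance of higher and lower genes depends on the scaling: it was 44 higher and 174 lower with repeated quantile normalization, and 69 and 59 with median centring. Over all clusters, with the scaling unchanged, it was 318 and 140. The block held 62 such genes and the separate variances 159. The 95% interval of the difference lay within 2-fold either way for 17215 genes (93.5%). It was far wider for some macrophage markers, such as FABP4 (-4.63 to 3.57), where a large difference is not excluded. In this fit a difference of 1 or more in size was seen in 3 of the genes that can be named here: EGR1 (-1.46, SE 0.79), an immediate early transcription factor, FN1 (-1.17, SE 1.32), fibronectin, and GAL (-1.06, SE 0.68), the neuropeptide galanin, and none passed the test. GAL was chosen after its values were seen. The 6 values of each label did not overlap in 3 genes, BCL7C (-0.18), GUCA1C (0.18) and ZNF81 (0.30). This is 0.0163% of genes where chance gives 0.216%, again a poor reference for arrays that fall into clusters. These 3 were chosen in the same way. A difference of 1 sign in all 6 donor pairs was seen in 126 genes (0.686%), where 6 independent pairs give 3.12%. That share needs 6 pair differences that are independent of each other. Arrays that fall into clusters do not give this, and no conclusion is drawn from the shortfall.

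In every one of the 35 gene lists, 0 members passed the threshold over all genes and 0 passed when adjusted over the list alone. Camera with its preset correlation placed 3 lists past the threshold. All 30 measured cell cycle and DNA replication genes had lower means in arrays labelled macrophage, with a median difference of -0.23 (camera adjusted p = 2.635e-07, against an adjusted p = 0.9963 with an estimated correlation). Among them PLK1, a mitotic kinase, differed by -0.57 (SE 0.44) and RRM2, a ribonucleotide reductase subunit, by -0.49 (SE 0.34). Of 23 pattern recognition and inflammasome genes, 19 had higher means and the median was 0.15 (camera adjusted p = 0.003226, against an adjusted p = 0.9963 with an estimated correlation), with NOD2 at 0.39 (SE 0.39) and TLR7 at 0.38 (SE 0.28). In the MHC class II presentation list 13 of 15 genes had higher means, with a median of 0.12 (camera adjusted p = 0.004618, against an adjusted p = 0.9963 with an estimated correlation). Its members HLA-DPB1 and HLA-DPA1 differed by 0.43 (SE 0.30) and 0.38 (SE 0.29). A single low array labelled monocyte weighs on each difference: HLA-DPB1 was at 10.92 with the next at 12.63, and HLA-DPA1 at 10.96 with the next at 12.62. With the estimated correlation 0 of 35 lists passed, in this fit or in any of the 20 other fits with another setting or without 1 array, and fry gave an adjusted p of 0.977 for each of the 3. Whether camera with that correlation could find a shifted list in these arrays was not tested. Each call also ended when 1 array was left out. The cell cycle call ended without monocyte replicate 5 (camera adjusted p = 0.1376), the pattern recognition call without monocyte replicate 5 (camera adjusted p = 0.1459) or without macrophage replicate 1, 2 or 5, and the MHC class II call without monocyte replicate 3 (camera adjusted p = 0.3244) or macrophage replicate 3 (camera adjusted p = 0.0994). At the preset correlation 16 of the other 32 lists passed in at least 1 other fit. The sign of a list's median, its mean and the camera direction did not all coincide in 10 of the lists below, whose medians ran from -0.03 to 0.03.

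Markers of the cell states did not separate the labels. In the classical monocyte list 17 of 19 measured genes had higher means in arrays labelled macrophage, with a median of 0.13 (camera adjusted p = 0.1423). With array weights the median was 0.40 (camera adjusted p = 0.008062, against an adjusted p = 0.9825 with an estimated correlation), and without monocyte replicate 1 or 4 or macrophage replicate 3, 4 or 6 it was between 0.24 and 0.50, past the threshold at the preset correlation only. CCR2, the receptor for the chemokine CCL2, differed by 0.39 with a 95% interval from -1.66 to 2.44, and CDA, cytidine deaminase, by 0.33 (SE 0.30). For non-classical monocyte genes the split was 6 higher and 9 lower (median -0.02), with CX3CR1, the fractalkine receptor, at 0.63 (95% interval -1.96 to 3.21) and FCGR3A (CD16) at 0.30 (SE 0.42). Macrophage markers were 14 higher and 15 lower with a median of -0.01, and single arrays set its sign: without 1 array it ran from -0.54 to 0.36, and it passed the preset correlation with a positive median without monocyte replicate 2 (0.26) or macrophage replicate 2 (0.32) or 5 (0.36). With an estimated correlation the lowest of these 3 adjusted p-values was 0.947. Beside FN1, TREM2, a lipid-sensing receptor, differed by -0.57 (95% interval -3.03 to 1.89). Their median SD within a label was 1.87, against 0.243 over all genes. Transcription factors of the lineage were 8 higher and 11 lower (median -0.03), with NR1H3, the liver X receptor alpha, at -0.40 (SE 0.61) and BHLHE41 at -0.32 (SE 0.74). In the CSF1 receptor signalling list 13 of 19 genes had lower means (median -0.11), with CCND1 (cyclin D1) at -0.61 (SE 0.62), SPRY2 at -0.55 (SE 0.51) and the ligand CSF1 at -0.45 (95% interval -2.38 to 1.48).

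Lists of uptake and degradation genes had small medians. Lysosome genes were 14 higher and 18 lower (median -0.03), but passed at the preset correlation with a positive median, between 0.09 and 0.11, without monocyte replicate 2 or 5 or macrophage replicate 2 or 5. The lowest of these 4 adjusted p-values with an estimated correlation was 0.947. The list holds the protease CTSL at -0.36 (SE 0.72) and the proton pump subunit ATP6V0D2 at -0.30 (95% interval -3.64 to 3.05). Phagocytic and scavenger receptors were 13 higher and 11 lower (median 0.01). MARCO, a scavenger receptor, was higher in the array labelled macrophage of 6 of 6 donor pairs, by 0.49 (SE 0.27), without passing the test, and COLEC12 differed by 0.32 (SE 0.83). Complement genes were 16 higher and 3 lower (median 0.17, camera adjusted p = 0.07023, but 0.02727 with repeated quantile normalization, 0.01685 with ranks and 0.001082 with components 1 and 2 as covariates). With an estimated correlation the adjusted p was 0.9963 in the full fit, 0.9836 with quantile normalization and 0.1504 with the components. Its members were led by VSIG4, a complement receptor, at 0.32 (SE 0.70) and CD59 at 0.31 (SE 0.79). For iron, heme and oxidative stress genes 8 were higher and 14 lower (median -0.05), with CP (ceruloplasmin) at -0.41 (SE 0.37) and SLC11A1 at -0.25 (SE 0.54). The metallothionein list, which also holds genes that are not metallothioneins, was 5 higher and 5 lower (median 0.00). It holds MT2A at -0.10 (SE 0.24) and MT1E at -0.10 (SE 0.38).

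Cholesterol biosynthesis genes were 10 higher and 8 lower (median 0.03), with SC5D at 0.30 (SE 0.62) and MVD at -0.23 (SE 0.21). Of 14 cholesterol efflux and liver X receptor target genes 11 had lower means (median -0.12), with the phospholipid transfer protein PLTP at -0.60 (95% interval -2.81 to 1.61) and APOE (apolipoprotein E) at -0.45 (SE 0.58). Fatty acid and lipid droplet genes were 7 higher and 17 lower (median -0.09). LPL, lipoprotein lipase, differed by -0.53 (95% interval -3.39 to 2.33) and FABP4, a fatty acid carrier, by -0.53 (95% interval -4.63 to 3.57). Glycolysis genes were 4 higher and 15 lower (median -0.13, camera adjusted p = 0.127), and passed at the preset correlation with the dim-gene filter (0.02953) and without monocyte replicate 1 or 4 or macrophage replicate 1 or 4 (lowest 5.461e-05). With an estimated correlation the adjusted p was 0.9563 with that filter. Among them were ENO2 at -0.43 (SE 0.77) and PFKP at -0.40 (SE 0.47). Oxidative phosphorylation and citrate cycle genes were 7 higher and 21 lower (median -0.07), and passed at the preset correlation without monocyte replicate 3 (0.001153, against an adjusted p = 0.9597 with an estimated correlation) or 6 or macrophage replicate 3, with COX5B at -0.28 (SE 0.25) and ATP5MC1 at -0.25 (SE 0.17). Endoplasmic reticulum stress genes were 14 higher and 10 lower (median 0.03), with VLDLR at -0.24 (SE 0.51) and PHGDH, the first enzyme of serine synthesis, at 0.23 (SE 0.34).

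Of 19 immediate early genes, 18 had lower means in arrays labelled macrophage (median -0.19, camera adjusted p = 0.07023). This list passed the threshold with the dim-gene filter (camera adjusted p = 0.007551), median centring (0.02403), ranks (0.04211) or components 1 and 2 as covariates (3.464e-11), and without monocyte replicate 2, 3 or 6 or macrophage replicate 2 or 5. These calls rest on the preset correlation: the adjusted p with an estimated correlation was 0.9963 in the full fit and 0.1504 with the components. EGR1 was at 10.16 ± 1.67 and 8.70 ± 1.37 (SD, n = 6 each), and EGR3 differed by -0.63 (SE 0.40). Type I interferon-stimulated genes were 7 higher and 20 lower (median -0.09), with USP18 at -0.45 (SE 0.29) and LY6E at -0.35 (SE 0.33). Inflammatory cytokine genes were 11 higher and 15 lower (median -0.01), with the soluble pattern receptor PTX3 at -0.65 (SE 0.40) and IL1RN, the interleukin 1 receptor antagonist, at -0.55 (SE 0.48). IL1RN also belongs to the alternative activation list, which was 10 higher and 10 lower (median 0.01) and in which F13A1, a coagulation factor subunit, differed by 0.60 (SE 0.47). Chemokine receptor genes were 10 higher and 7 lower (median 0.05), led by CX3CR1 and CCR2. Matrix remodelling genes were 6 higher and 17 lower (median -0.07), with FN1 first and THBS1 (thrombospondin 1) at -0.57 (95% interval -3.14 to 1.99). Cytoskeleton, adhesion and fusion genes were 4 higher and 21 lower (median -0.11), with the fusion protein DCSTAMP at -0.63 (95% interval -3.94 to 2.69) and ITGB3 at -0.38 (SE 0.54).

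Markers of other cell types also lay within the spread between arrays. T cell markers were 12 higher and 4 lower (median 0.07), with IL7R at 0.36 (SE 0.88) and GZMK at 0.32 (SE 0.89). Natural killer cell markers were 6 higher and 12 lower (median -0.04), with GNLY at -0.27 (SE 0.45) and KLRB1 at 0.23 (SE 0.46). B cell markers were 10 higher and 4 lower (median 0.05), with BANK1 at 0.25 (SE 0.40) and FCER2 at 0.24 (SE 0.43). Platelet markers were 12 higher and 5 lower (median 0.03), with ITGB3 first and TREML1 at -0.34 (SE 0.35). Neutrophil markers were 9 higher and 9 lower (median 0.00), with CXCR1 at -0.64 (SE 0.37) and ALPL at -0.45 (SE 0.35). Erythroid markers were 9 higher and 3 lower (median 0.04), with HBB (beta globin) at 0.43 (95% interval -2.07 to 2.93) and CA1 at 0.24 (SE 0.55). Dendritic cell markers were 8 higher and 9 lower (median 0.00), with FCER1A at 0.48 (SE 0.71) and CD1C at 0.45 (SE 0.69). Basophil and mast cell markers were 4 higher and 5 lower (median -0.02), with CPA3 at 0.47 (SE 0.82) and CLC at 0.31 (SE 1.22). Fibroblast and endothelial markers were 5 higher and 11 lower (median -0.08, camera adjusted p = 0.127), with PDGFRA at -0.18 (SE 0.09) and COL6A3 at -0.17 (SE 0.21).

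The arrays differed among themselves far more than the labels did. Over the 12 arrays 1424 genes spanned at least 2 on the log2 scale and 174 at least 4. FABP4 ran from 3.33 to 11.8, DCSTAMP from 4.36 to 11.8, FN1 from 5.20 to 12.2 and HBB from 5.33 to 11.1. In 102 genes the sorted values held a gap of at least 2, and in 0 of them did the gap separate the labels. In 50 of the 102 the gap left 4 arrays below it, 2 of each label in all 50, and in 46 it left 8 arrays below it, 4 of each label in all 46. Pairs of arrays with the same label correlated at 0.966 ± 0.015 (SD, 30 pairs) and pairs with different labels at 0.969 ± 0.015 (SD, 36 pairs). The most similar other array carried the same label for 5 of 12 arrays, where the mean over all splits is 5.45.

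**Figure D2:**
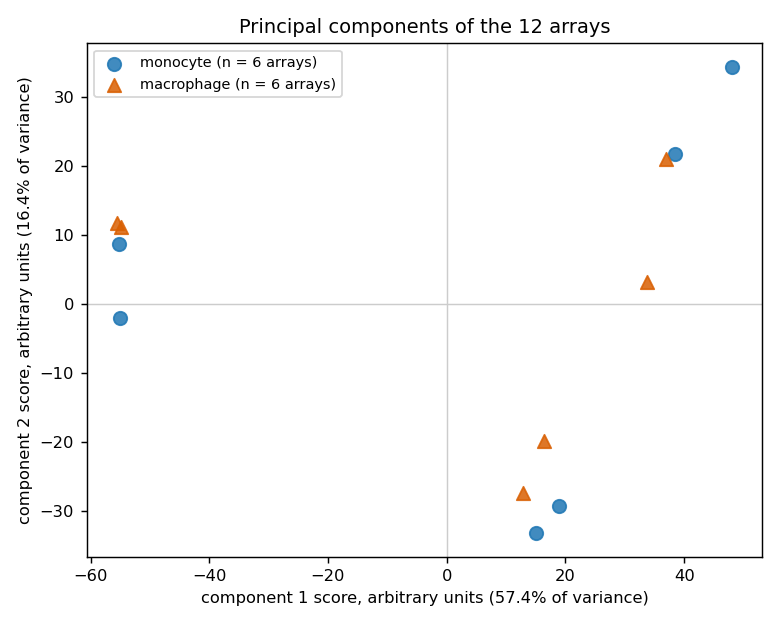
Scores of the 12 arrays on the first 2 principal components (arbitrary units), with circles for arrays labelled monocyte and triangles for arrays labelled macrophage (n = 6 each). Component 1 held 57.4% and component 2 held 16.4% of the variance, and each cluster of points holds both labels.

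Neither leading component followed the labels. On component 1, arrays of each label lay between -55.5 and -54.9, between 12.9 and 18.8, and between 33.7 and 48.0. No array lay outside these ranges. Scores on component 1 differed by -3.46 between the label means with SDs of 45.6 and 42.5 (exact permutation test over all splits, two-sided, p = 0.788), those on component 2 by -0.07 (exact permutation p = 0.998) and those on component 3 by 7.85 (exact permutation p = 0.442). The labels held 2.71% of the total variance, and 413 of the 462 splits of the arrays into 6 and 6 held as much or more (exact permutation p = 0.894, one-sided).

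**Figure D3:**
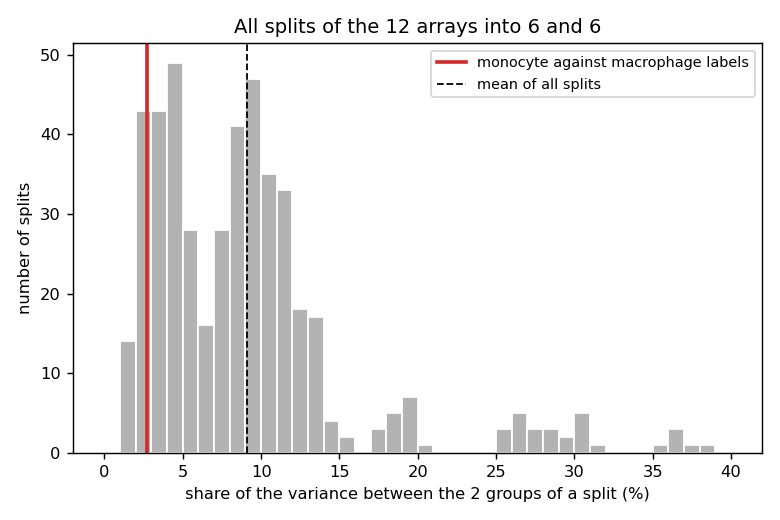
Number of splits (vertical axis) by the share of the variance between their 2 groups (%, horizontal axis), over all 462 splits of the 12 arrays into 6 and 6. The monocyte and macrophage labels (red line) lie at 2.71%, below the mean of 9.09% (dashed line), and the highest split reaches 38.4%.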

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

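All the results in this part are single arrays that stood apart from the other 5 of their label, with a gap to the nearest array, divided by the range of the 6, above Dixon's 95% critical value for 6 values. Of 210 sets of 6 values examined, 12 were over it. Chance alone gives about 1 in 20, so the number is close to what chance gives, and in sets that fall into clusters the ratio has no clear meaning.

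CA1, carbonic anhydrase 1, an erythroid marker, was at 6.28 in 1 array labelled monocyte with the next at 4.55 (ratio 0.845), and at 7.48 in 1 array labelled macrophage with the next at 4.60 (ratio 0.867). The mean of the erythroid list was 6.63 against 5.96 (ratio 0.828) and 6.89 against 6.19 (ratio 0.630) in the same way, while HBB, the other erythroid gene examined, was under the critical value with both labels.

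FN1 was at 12.2 in 1 array labelled macrophage, with the next at 6.75 (ratio 0.779). RRM2 was at 7.31 against 6.47 (ratio 0.678), MT2A at 12.6 against 11.7 (ratio 0.636) and COL6A3 at 6.41 against 5.55 (ratio 0.738), each in the highest array labelled macrophage. On the low side, CSF1R was at 10.2 against 10.6 in arrays labelled macrophage (ratio 0.629), and the mean of the CSF1 receptor signalling list was 8.40 against 8.62 in arrays labelled monocyte (ratio 0.697). HLA-DPB1 and HLA-DPA1 were lowest in 1 array labelled monocyte each, at 10.9 against 12.6 (ratio 0.841) and 10.96 against 12.62 (ratio 0.806).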

How the results depend on the processing

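The count of 0 genes past an adjusted p of 0.05 was the same under the replicate block, the dim-gene filter, repeated quantile normalization, median centring, the mean of clusters, trend and robust eBayes, array weights, all clusters, the Welch statistic, an adjusted p of 0.01 and without any one array, and with the 2 components as covariates. Unadjusted counts ranged from 32 genes with the dim-gene filter to 655 with those components, chosen after seeing the data, as was the estimated correlation in fits other than the full one. None of the 70 named genes passed in any of these fits. Of these genes 2 differed by 1 or more in size in the full fit, 6 with array weights and between 1 and 10 without one array. Differences moved by over 1.5 times in 33 of them with array weights, 10 with the components, 3 with quantile normalization, 1 with centring and between 19 and 45 without one array. In the fit paired by donor number (replicate block) 0 genes and 3 lists passed, and no call changed. Values that never passed have no established direction: of 840 values for named genes without one array, 52 had another sign than in the full fit, as did 4 of 549 under other settings, and for lists, whether past the threshold or not, 110 of 420 and 27 of 350. The count of lists moved from 3 to 0 with an estimated correlation, to 5 with the dim-gene filter, array weights or components 1 and 2 as covariates, to 6 with ranks, and to between 2 and 9 without one array. With the estimated correlation 0 lists passed in any of 21 fits, the full fit, other settings and those without one array included (lowest adjusted p 0.1504, with the components). The medians then stay at -0.2333 (cell cycle), 0.1469 (pattern recognition) and 0.1172 (MHC class II) and lose their calls. Lists that gained a call, with their medians, were glycolysis (-0.1317) and immediate early genes (-0.1929) with the dim-gene filter, complement (0.1671) with quantile normalization, immediate early genes (-0.1728) with centring, classical monocyte (0.4006) and fibroblast and endothelial markers (-0.09548) with array weights, classical monocyte (0.1282), complement (0.1715) and immediate early genes (-0.1947) with ranks, and complement (0.1964) and immediate early genes (-0.2905) with the components. Leaving out 1 array gave lists uncalled in the full fit 37 calls with the sign of the full-fit median, in 14 lists, and 8 with the opposite sign, in 3. In what follows, numbers after a label name the replicates whose removal gave the call. Without one array the medians ranged from -0.0781 to 0.4972 for classical monocyte markers (monocyte 1, 4, macrophage 3, 4, 6), -0.05403 to 0.1374 for phagocytic receptors (macrophage 5), 0.01823 to 0.221 for complement and -0.5378 to 0.07316 for immediate early genes (both monocyte 2, 3, 6, macrophage 2, 5), -0.2278 to -0.04443 for glycolysis (monocyte 1, 4, macrophage 1, 4), -0.1466 to 0.01481 for oxidative phosphorylation (monocyte 3, 6, macrophage 3), -0.2618 to 0.0208 for interferon-stimulated genes (monocyte 3, 6, macrophage 5), -0.2216 to -0.003672 for cytoskeleton (monocyte 1, 4, macrophage 3), -0.1389 to 0.4203 for T cells and -0.05258 to 0.1291 for B cells (both monocyte 4, macrophage 3), -0.1108 to 0.1644 for neutrophils and -0.06629 to 0.1469 for erythroid markers (both monocyte 1) and -0.1145 to -0.02703 for fibroblast and endothelial markers (macrophage 6). Calls with the opposite sign of the full-fit median appeared for macrophage markers (range -0.5395 to 0.3609) without monocyte replicate 2 (0.2627) or macrophage replicates 2 (0.3204) or 5 (0.3609), for lysosome (range -0.1623 to 0.1063) without monocyte replicates 2 (0.1037) or 5 (0.1063) or macrophage replicates 2 (0.09599) or 5 (0.09219), and for natural killer cells (range -0.1724 to 0.1027) without monocyte replicate 4 (0.1027), while without macrophage replicate 5 they gained a call at -0.1724. The 3 called lists ranged from -0.3735 to -0.1304 (cell cycle), 0.03781 to 0.2763 (pattern recognition) and 0.05035 to 0.2126 (MHC class II). The cell cycle call ended without monocyte replicate 5 (-0.1304, camera adjusted p = 0.1376), the pattern recognition call without monocyte replicate 5 (0.03781) or macrophage replicates 1 (0.05658), 2 (0.08246) or 5 (0.07032), and the MHC class II call without monocyte replicate 3 (0.06318) or macrophage replicate 3 (0.05035). The cause was not tested. Low values could not be told from background.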

Other observations

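Component tests in this part were chosen after the spread of the arrays was seen, as were the column-order test, the shuffles and the fit with components as covariates. The counts over splits of the arrays were planned. Component 1 was turned so that macrophage markers are positive, so the side they lie on is set by that choice. Against random lists matched on expression, 23 of the 35 fixed lists had a median above or below all 10000, so such a position does not set 1 list apart from another. Of 29 macrophage markers, 28 were positive, with a median of 1.62 on the log2 scale per SD of the score. Genes are named in this part by their loadings, after their values were seen. The largest on this side were SPP1 (3.76), FABP4 (3.36), SELENOP (3.25), A2M (3.00) and GPNMB (2.96). All 32 lysosome genes (median 0.46) and all 18 cholesterol biosynthesis genes (median 0.50) were positive too. On the negative side lay 17 of 19 classical monocyte markers (median -1.0), led by S100A12 (-2.89) and VCAN (-2.37), and 18 of 19 immediate early genes (median -1.03) such as FOSB (-2.16). All 16 T cell markers (median -0.85), 17 of 18 natural killer cell markers (median -0.48) and 17 of 18 neutrophil markers (median -0.39) were negative as well.

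Component 2 was turned in the same way by interferon-stimulated genes. On it 24 of 27 of these genes were positive (median 0.46), among them IFI44L (1.28), MX1 (0.87) and OAS3 (0.84), as were all 28 oxidative phosphorylation and citrate cycle genes (median 0.24). The genes CHIT1 (1.39) and CSF1 (1.15) were high on the same side, while 17 of 29 macrophage markers (median -0.14) and all 16 T cell markers (median -0.23) were negative. The other side held 16 of 19 glycolysis genes (median -0.20) and 8 of 10 genes of the metallothionein list (median -0.27). EGLN3 (-1.77), BNIP3 (-1.31), SLC2A1 (-1.41) and HILPDA (-1.30) had large loadings there, and so did VCAN (-1.77), FN1 (-1.27) and SPP1 (-1.11). EGLN3 was between 5.88 and 6.63 in 8 arrays, 4 of each label, and between 9.62 and 10.5 in the other 4.

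No gene passed the test between the labels while arrays of each label differed widely in macrophage and monocyte genes. Noise that is independent between genes is argued against: component 1 held 57.43% of the variance, where 100 shuffles of each gene over the arrays gave at most 10.69%. Differences in array quality that many genes share give no reason for genes to sort by cell type. On component 1, 28 of 29 macrophage markers were positive (median 1.62) and 17 of 19 classical monocyte markers negative (median -1). Both medians lay beyond those of all random lists matched on expression. Array medians ran only from 6.15 to 6.34, and ACTB spanned 0.29. These values argue against such quality differences for these markers. For other genes they stay open. An unlabelled factor that masks a label effect stays open. With components 1 and 2 as covariates 0 genes passed by label, in a fit that recovered 96.2% of 2-fold changes planted in genes drawn at random. But unadjusted genes went from 117 to 655, where the threshold alone gives 921. Without covariates the median over the other splits drawn was 415. List calls in the fit with components went from 3 to 5, with immediate early genes at a camera adjusted p of 3.464e-11 and complement at 0.001082, all at the preset correlation. With an estimated correlation 0 lists passed in that fit (adjusted p = 0.1504 for both). That labels or columns may be out of step with the arrays also stays open. For 12 of 12 arrays the most similar other array lies a multiple of 3 columns away in the deposited order. This spacing was noticed in the same correlations, so the count describes it and does not test it. Arrays of both labels held SPP1 between 12.3 and 13.1, and arrays of both labels held it between 4.55 and 5.14. The sources used here give no order of processing, so a factor tied to that order could not be told apart. A small or absent effect of M-CSF on these cells was not tested apart from the label comparison.

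The gene count of 0 could not be tested against other splits, since 100 of 100 splits of the arrays give at least 0 genes. Over the other splits the median was 0 genes, and 5 of the 100 called at least 1. The highest called 2334, which points to a structure of the arrays that the labels do not describe. For the list count chance could not be excluded. As many lists as the real 3 passed camera's preset correlation in 91 of 100 splits, with 27 in the highest other, and 0 lists passed with the estimated correlation in any of the 100. Of the 31 other splits that, like the labels, part all 6 donor pairs, 29 held as large a share of the variance as the labels, up to 36.0%. The 4 other such splits among the 100 called 0 genes each and up to 21 lists.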
